A study of Homo sapiens with 4 samples.

How the data were processed

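Total RNA from A375 cells, an established human melanoma line, was measured on 4 one-colour expression arrays, 2 of parental cells and 2 of a derived line resistant to dabrafenib and trametinib. Per the labels' protocols, RNA was extracted with Trizol, amplified and labelled with Cy5 as cRNA. The labels describe the arrays of each group as biological replicates 1 and 2. They do not say that these came from separate cultures, so the p-values measure only the spread between these arrays, which may be technical. Both groups carry the same treatment text, and whether inhibitor was in the medium at harvest is not given in the sources used here.

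The table deposited by the authors holds probe intensities on a linear scale as whole numbers from -2 to 65511. Values below 0 show that some background had been subtracted before deposit. The scanner, the background method, any filter on probes and any scaling are not given in the sources used here, and no detection flags were used here. The deposited intensity columns had medians of 119 and 127 units in the parental arrays and 156 and 161 units in the resistant arrays. Their log2 medians and quartiles differed by up to 0.459, above the limit of 0.1 set for a table that counts as normalized between arrays.

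The 31741 probes were named through the platform annotation. A single gene was named for 24658 probes, several genes for 1002 and none for 6081. Of the single symbols, 22404 were current in the reference gene table (GRCh38.p14), 2177 were updated through its synonyms and 77 were kept as given, which left 18255 genes. Some genes of the lists described here, and some of those chosen in advance for their role, had no probe named for them alone in the tables used and are not analysed here. The genome build behind the probes is not given in the sources used here, so no coordinates are printed, and the reference table served only for symbols, chromosomes and the order of neighbours.

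Values at or below 0 were set to the lowest positive value of their array. The values were then logged (base 2) and quantile-normalized between the 4 arrays. Changes are resistant minus parental and so are relative to the overall brightness of the arrays. Before normalization the median probe was 0.339 higher on the log2 scale in the resistant arrays, or 1.26 times brighter. Group means and SDs are given in normalized intensity units, over 2 arrays per group. Intensities quoted per array are those deposited. Linear models were fitted with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a trend on intensity), and p-values were adjusted by the Benjamini-Hochberg method over all 31741 probes. The threshold was an adjusted p of 0.05. The fit had 2 residual and 1.32 prior degrees of freedom, and the number of arrays limits the precision. Where a gene had several probes, the probe with the highest mean over the 4 arrays stood for it. Of 5450 genes with several probes, 976 had at least 2 past the threshold, and in 64 of these such probes went in opposite directions.

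The 32 gene lists were tested with camera at a preset correlation of 0.01 and adjusted over all lists. Estimated correlations and fry, a rotation test of whether a list moves one way without comparing it with other genes, were alternatives. Estimated correlations rest on the same 2 residual degrees of freedom. None of the 7 lists past the threshold passed it with an estimated correlation. That correlation lay above the preset 0.01 for MAPK output (0.0431) and heat shock and RNA quality (0.205). It lay below for cholesterol synthesis (-0.0276), fibroblast markers (-0.043), the epithelial-mesenchymal transition (-0.00653), p53 targets (0.00539) and hypoxia and glycolysis (0.0071). In the latter lists the failure cannot come from a correlation above the preset one. With so few residual degrees of freedom nothing is concluded from it. The lists, tests and alternatives were fixed before the data were examined, except where stated. The rule for named genes took EDN1, EDNRB, AKT1, AKT2, MITF and other genes not analysed here. It also took the 12 largest rises and the 12 largest falls among genes past the threshold whose groups did not overlap and whose higher group lay above the median of all probes. From each list it took up to 4 members with the smallest p. Genes outside this rule are said to be so.

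The tests were tried on simulated data with the spread of these arrays, in which 100 of 31741 probes were changed by 1 and 100 by 0.5 on the log2 scale. All changed probes were drawn from those brighter than the median in parental cells. The tests recovered 59% of the changes of 1 and 12% of those of 0.5, and these rates hold for such bright probes only. There were 45 false calls, or 38.8% of all calls, and all 45 lay among the dimmest 25% of probes, where whole-number values of a few units can have no spread. With that 25% left out there were 4 false and 151 true calls. This filter could not cost true calls, because no change was simulated among dim probes. With no change simulated there were 0 calls. These shares do not carry over to the real data, where 8693 probes were called, because the adjusted threshold depends on how many probes change. In the real data 656 of the called probes lie among the dimmest 25%, below 28.2 units on average.

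The alternatives were no normalization between arrays, median centring, leaving out the dimmest 25% or 50% of probes, no intensity trend, robust eBayes, an offset of 50 units before the log, the replicate number as a block, a test against a 1.5-fold change, the mean of all probes of a gene, and leaving out each array in turn. A crossed pairing of the replicates, and a fit without probes at the scanner ceiling (65500 units or more) or at or below 0, were added after the data were seen. The ceiling was reached on at least 1 array by 55 probes, and 443 probes lay at or below 0 on at least 1 array. Chance alone would leave the groups of 33.3% of probes without overlap, and 63.4% were so.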

Results

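Gene expression was compared between parental A375 cells, an established melanoma line (n = 2 arrays), and a line derived from them that is resistant to dabrafenib and trametinib (n = 2 arrays). Dabrafenib and trametinib inhibit successive kinases of the MAPK pathway. Per the labels, the cells had been exposed to rising concentrations of both drugs, 1 nM dabrafenib with 0.1 nM trametinib, then 10 nM with 1 nM, then 100 nM with 10 nM. The study asked about endothelin-1 and the kinase Akt in this acquired resistance. Probe intensities were measured for 31741 probes, of which those naming a single gene covered 18255 genes. Across probes, the replicate arrays correlated at r = 0.986 for parental and 0.992 for resistant cells on the log2 scale, and pairs of arrays from different lines at 0.972 to 0.974. Probes are not independent replicates, so these values only describe the arrays. A few spots stood apart on 1 array: 31 probes were below 10 normalized units on that array and above 100 on the others, 21 of them on parental replicate 2.

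EDN1, which encodes the vasoactive peptide endothelin-1, was 21.7 times higher in the resistant line. Its normalized intensity rose from 145 ± 2.3 (SD, n = 2) to 3140 ± 210 (SD, n = 2), a log2 change of 4.44 (SE 0.061, limma adjusted p = 0.000893). Both resistant arrays, at 3507 and 3326 units as deposited, lay far above both parental arrays, at 125 and 131. With 50 units added before the log, which damps folds of dim probes, the rise was 16.3-fold. ECE2, a homologue of the enzyme that makes mature endothelin, was 2.70 times lower (adjusted p = 0.0147), although its other probes changed by -0.07 and -0.68 on the log2 scale and did not pass the test. EDNRB, an endothelin receptor, had 426 ± 27.7 units in parental and 296 ± 38.8 units in resistant cells (SD, n = 2; log2 change -0.53, adjusted p = 0.0589), and its other probes both had a log2 change of -0.08. ECE1, the main endothelin-converting enzyme, had a log2 change of -0.15 (adjusted p = 0.135), which passed with median centring (-0.24, adjusted p = 0.0367) and turned without normalization (0.13, adjusted p = 0.301). Of the 6 members of the endothelin system measured, 1 was higher, 1 was lower and 4 did not pass the test, against 1 higher and 2 lower when adjusted over the list alone. The list as a whole did not pass (camera adjusted p = 0.618), and its median (-0.34) and mean (0.27) differed in sign. With any 1 array left out, the EDN1 change stayed between 4.39 and 4.52 but its adjusted p rose to between 0.061 and 0.0683, and EDNRB passed the threshold in several other settings, for example with median centring (-0.60, adjusted p = 0.0191).

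Of 23 components of the PI3K-AKT-mTOR pathway, 5 were higher, 3 were lower and 15 did not pass, against 6 higher and 3 lower when adjusted over the list alone. Without normalization 10 were higher and 3 lower, and with median centring 4 were higher and 4 lower. PIK3R3, a regulatory subunit of PI3-kinase, was 2.48 times higher (adjusted p = 0.00121), while its second probe did not pass (1.24 times, adjusted p = 0.0574). PIK3R1, another regulatory subunit and dim in parental cells at 45.0 units, was 1.67 times higher (1.32 times with 50 units added before the log). INPP4B, a phosphatase that acts on PI3-kinase products, was 2.20 times lower, and the adaptor GAB2 was 1.70 times lower. AKT1 had 1487 ± 29.5 units in parental and 1709 ± 178 units in resistant cells (SD, n = 2; log2 change 0.20, adjusted p = 0.203), and its second probe had a log2 change of 0.49 (adjusted p = 0.0729). AKT2 had 148 ± 3.0 and 135 ± 3.7 units (SD, n = 2; log2 change -0.12, adjusted p = 0.176). Transcript levels say nothing of the phosphorylation of these kinases. The list did not pass as a whole (camera adjusted p = 0.607). Without normalization AKT1 passed the test (0.46, adjusted p = 0.0223) and AKT2 turned its direction without passing (0.24, adjusted p = 0.0826), in a setting where the median probe was 0.339 higher. Of 18 targets of the FOXO transcription factors, which Akt holds out of the nucleus, 9 were higher, 6 were lower and 3 did not pass, with the same numbers when adjusted over the list alone. GADD45A was 2.35 times and the ubiquitin ligase FBXO32 1.88 times higher, while the receptor ERBB3 was 12.9 times and the insulin receptor substrate IRS2 6.33 times lower. A second IRS2 probe lay at or below 0 on all arrays. The median of the FOXO list (0.18) and its mean (-0.20) differed in sign, and it did not pass (camera adjusted p = 0.618).

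Genes that the MAPK pathway switches on were lower in the resistant line. Of 22 measured, 20 were lower, 0 were higher and 2 did not pass the test, against 21 lower when adjusted over the list alone, and the median member was 3.31 times lower. PHLDA1 was 17.3 times lower, from 6804 ± 160 to 394 ± 17.2 units (SD, n = 2; log2 change -4.11, SE 0.046, adjusted p = 0.000839), and its second probe was 4.31 times lower. The ERK phosphatase DUSP6 was 16.7 times lower, the immediate early transcription factor EGR1 14.5 times lower and the ETS factor ETV4 8.74 times lower. DUSP6 and EGR1 were dim in resistant cells, at 40.5 and 27.9 units, and fell 8.02-fold and 5.83-fold with 50 units added before the log. The members that did not pass were MAFF and MYC, and the MYC probe lay at only 2.11 and 6.05 units on average. The list passed at a camera adjusted p of 1.27e-12 with the preset correlation, but not with an estimated one (adjusted p = 0.413 with an estimated correlation). In the same arrays 8 of 12 heat shock and RNA quality genes were lower (camera adjusted p = 0.0338, adjusted p = 0.645 with an estimated correlation), among them the early response genes FOS and FOSB. Without normalization 2 of that list were higher and 2 lower, although the list passed there as lower, relative to other genes (camera adjusted p = 0.00546). Among 15 components of the pathway itself, 2 were higher, 4 were lower and 9 did not pass, with the same numbers when adjusted over the list alone (camera adjusted p = 0.393). The kinase gene MAPK3, which encodes ERK1, was 1.86 times lower, and MAP3K8, which encodes a kinase that activates MEK, was 1.80 times higher (adjusted p = 0.00816).

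**Figure D1:**
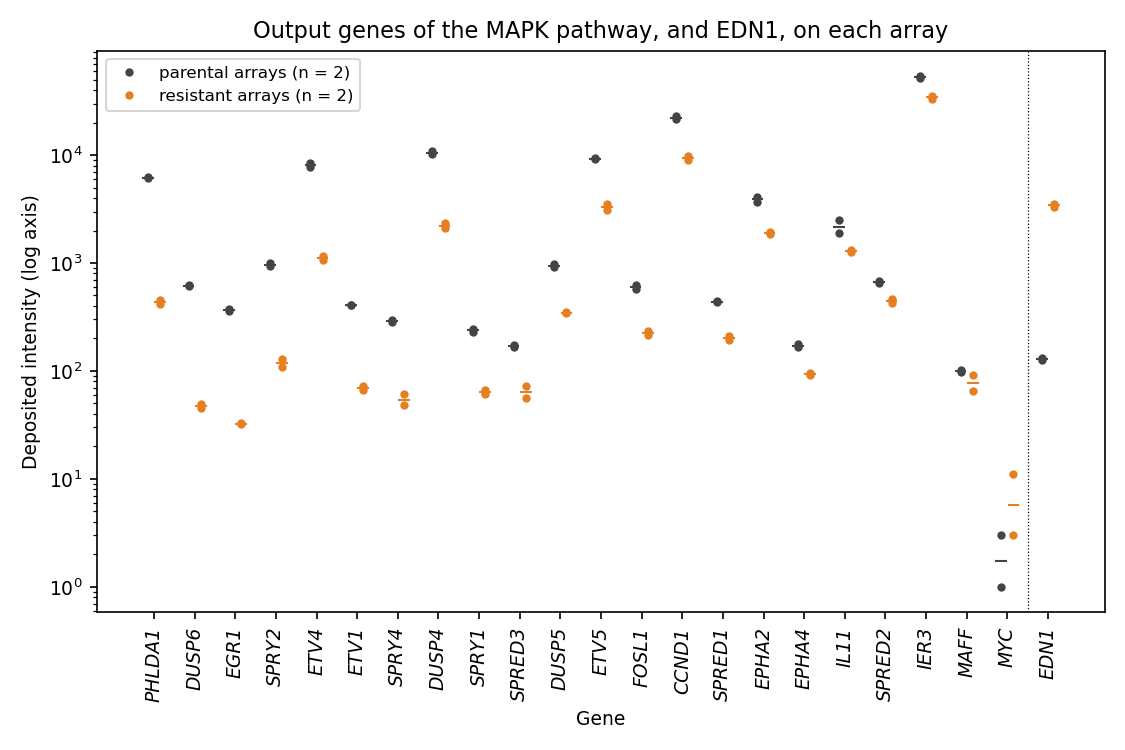
Deposited intensity (log axis) of the 22 MAPK output genes, ordered by their change, and of EDN1 at the right, on the 2 parental (grey) and 2 resistant (orange) arrays, with each short line at the geometric mean of a group. For 20 of the 22 genes both resistant arrays lie below both parental arrays and the test was passed, and EDN1 lies at 125 and 131 units in parental against 3507 and 3326 units in resistant cells.

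Of 30 receptor tyrosine kinases, 3 were higher, 9 were lower and 18 did not pass, with the same numbers when adjusted over the list alone. FGFR3 was 5.11 times (3.07 times with 50 units added before the log), EGFR 2.65 times and EPHA2 2.46 times lower. All 3 probes of ERBB3 fell, by 8.90, 2.88 and 2.60 times with 50 units added, and the other EGFR probes, which were dim, by 1.19 and 1.98 times. The receptor list did not pass (camera adjusted p = 0.0811). It passed as lower, relative to other genes, without normalization (camera adjusted p = 0.0313). Its median turned there from -0.14 to 0.14, but the median probe was 0.339 higher. Of 30 growth factor ligands, 12 were higher, 9 were lower and 9 did not pass, against 12 and 10 when adjusted over the list alone (camera adjusted p = 0.618). TGFA, a ligand of the EGF receptor, fell from 1976 ± 132 to 100.7 ± 5.0 units (SD, n = 2), or 19.6 times (adjusted p = 0.00104). BMP2 was 3.31 times, VEGFA 2.71 times and BMP4 2.53 times lower, with 2.20 and 1.57 times at the second probes of BMP2 and VEGFA.

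Over all probes, 4267 were higher and 4426 were lower in the resistant line, so that 49.1% of the called probes were higher. At least 2-fold changes numbered 794 higher and 962 lower. Counted by gene, 2728 were higher and 2909 lower. The balance depends on the scaling: 12274 probes were higher and 1870 lower (86.8% higher) without normalization, and 39.6% of called probes were higher with median centring. With any 1 array left out, a group is a lone array and the limma calls were lost, as set out below. All 8693 called probes kept their direction. That was nearly fixed in advance, because a called change is large beside the spread between replicates.

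**Figure D2:**
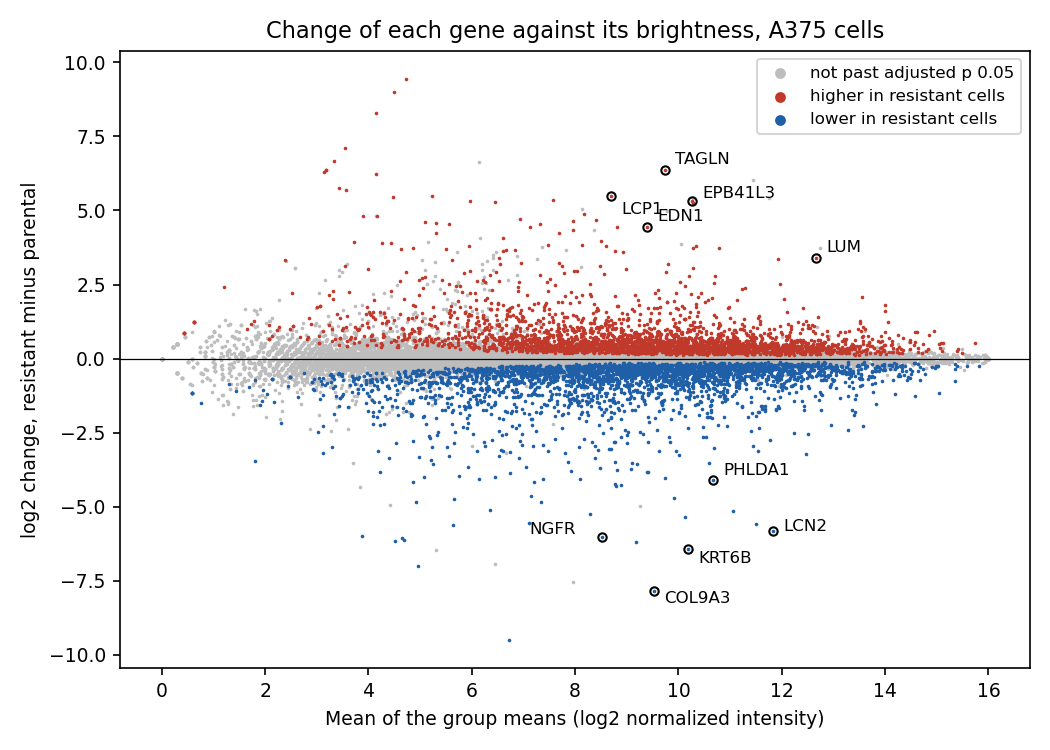
Change of each gene (log2, resistant minus parental) against the mean of its group means (log2 normalized intensity), for the 18255 genes, with those past an adjusted p of 0.05 in red (higher, 2728 genes) and blue (lower, 2909 genes). Grey points are genes that did not pass, whatever the size of their change. Circles mark EDN1 (4.44) and TAGLN (6.37) above, and COL9A3 (-7.86) and KRT6B (-6.41) below, with 6 more named genes.

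Among the 12 largest rises, TAGLN, an actin-binding protein of smooth muscle, rose from 94.0 ± 2.4 to 7762 ± 126 units (SD, n = 2; 82.5-fold, log2 change 6.37, SE 0.035, adjusted p = 0.000761), or 54.1-fold with 50 units added before the log. The actin-bundling gene LCP1 rose 44.5-fold, with a log2 change of 5.48, or 4.64 with 50 units added, and EPB41L3, which links membrane proteins to the cytoskeleton, rose 40.1-fold. The second EPB41L3 probe was dim in parental cells, at 11.6 units, and rose 8.93-fold with 50 units added. HSD17B6, a steroid dehydrogenase, read 1 and -1 units in parental cells and 734 and 800 in resistant cells. RBFA, which acts in mitochondrial ribosome assembly, went from 1 and 0 to 541 and 594 units, and RTN1, a reticulon of the endoplasmic reticulum, from -1 and -1 to 311 and 396 units. No fold is given for these, because the parental signal lay at about 0, and each rests on 1 probe. The cilium genes RSPH1 and CFAP58, the keratin KRT17, the protease inhibitor SPINK6, the zinc finger gene ZNF582 and the matrix gene POSTN were also dim in parental cells. With 50 units added before the log, their rises lay between 3.64-fold for ZNF582 and 15.7-fold for CFAP58, with 5.38-fold for POSTN and 7.47-fold for KRT17.

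Among the 12 largest falls, COL9A3, a collagen IX chain, fell from 11220 ± 61.4 to 48.4 ± 2.8 units (SD, n = 2; log2 change -7.86, SE 0.052, adjusted p = 0.000761), or 114-fold with 50 units added before the log. The keratin KRT6B was 85.2 times lower, the protease inhibitor SERPINA3 72.8 times lower (42.3 times with 50 units added) and LCN2, a siderophore-binding protein of inflammation, 56.1 times lower. NGFR, the low-affinity nerve growth factor receptor, fell from 2919 ± 227 to 45.9 ± 12.1 units (SD, n = 2; adjusted p = 0.00255), or 31.0-fold with 50 units added. HLA-DRA, a class II antigen-presenting chain, was 47.7 times lower, and its second probe was 24.3 times lower, or 16.1 times with 50 units added. The probe for the olfactory receptor gene OR4S1 read 2506 and 2674 units in parental and 5 and 4 units in resistant cells, a 53.3-fold fall with 50 units added. SULF1, SP8, PLA2G7, BIN3 and TFF2 lay below 10 units on average in resistant cells. With 50 units added, their falls lay between 4.61-fold for SP8 and 6.75-fold for TFF2.

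Markers of cell state moved in mixed directions. Of 23 melanocyte differentiation genes, 4 were higher, 9 were lower and 10 did not pass, against 5 and 10 when adjusted over the list alone. SOX10, a lineage transcription factor, was 2.88 times lower (adjusted p = 0.00102), CITED1 2.28 times, RAB38 2.12 times and CDK2, a cell cycle kinase, 1.75 times lower. MITF, the master regulator of pigment cells, was 1.13 times higher (adjusted p = 0.0457), a call that was lost, for example, with median centring (0.07, adjusted p = 0.339) and without the intensity trend (adjusted p = 0.0893). Of its 3 other probes, 1 passed. The melanocyte list did not pass (camera adjusted p = 0.393). It passed as lower, relative to other genes, without normalization (camera adjusted p = 0.0313). Its median turned there from -0.07 to 0.27, but the median probe was 0.339 higher. Of 24 genes of the dedifferentiated, invasive state, 6 were higher, 8 were lower and 10 did not pass, against 7 and 8 when adjusted over the list alone (camera adjusted p = 0.618). FGF2 was 3.43 times and the matrix gene TGFBI 1.85 times higher, opposite to NGFR and EGFR of the same list. Of 13 neural crest and neuronal markers, 2 were higher, 6 were lower and 5 did not pass, against 3 and 6 when adjusted over the list alone. S100B fell from 620 ± 14.1 to 34.7 ± 3.7 units (SD, n = 2), and the intermediate filament gene NES was 9.08 times lower. With 50 units added before the log the falls were 7.89-fold and 5.79-fold. This list did not pass (camera adjusted p = 0.425). It passed as lower, relative to other genes, without normalization (camera adjusted p = 0.0313). Its median turned there from -0.26 to 0.08, but the median probe was 0.339 higher.

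Of 19 epithelial-mesenchymal transition genes, 9 were higher, 2 were lower and 8 did not pass, against 10 and 2 when adjusted over the list alone. The median log2 change was 0.26 and the mean 1.15, since a few members rose steeply. Among these, TAGLN, MYL9, CNN1 and ACTA2 also belong to the smooth muscle family described later. MYL9, a myosin light chain of smooth muscle, was 21.9 times higher, the actin-associated CNN1 12.4 times and the transcription factor SNAI2 9.12 times higher. CNN1 and SNAI2 were dim in parental cells, at 27.7 and 30.9 units, and rose 5.06-fold and 4.09-fold with 50 units added. The list passed (camera adjusted p = 0.019), but not with an estimated correlation (adjusted p = 0.463 with an estimated correlation), without normalization (adjusted p = 0.207), with the dimmest 50% of probes left out (adjusted p = 0.107) or without resistant replicate 1 (adjusted p = 0.0701). Of 11 fibroblast markers, 7 were higher, 0 were lower and 4 did not pass, with the same numbers when adjusted over the list alone. The proteoglycan genes LUM and DCN were 10.5 and 4.29 times higher, LUM reaching 20980 ± 1202 units (SD, n = 2). The protease FAP was 5.51 times and the collagen chain COL1A1 3.30 times higher. The list passed (camera adjusted p = 0.00246), but not with an estimated correlation (adjusted p = 0.417 with an estimated correlation) or without normalization (adjusted p = 0.0627).

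Of 34 extracellular matrix genes, 14 were higher, 13 were lower and 7 did not pass, against 15 and 14 when adjusted over the list alone (camera adjusted p = 0.618). Without normalization 20 were higher and 8 lower. The matrix proteases MMP3 and MMP1 were 13.3 and 3.37 times higher, while MMP9 was 3.01 times and the protease inhibitor TIMP3 4.78 times lower. Of 22 targets of the transcriptional regulators YAP and TEAD, 11 were higher, 6 were lower and 5 did not pass, against 13 and 6 when adjusted over the list alone (camera adjusted p = 0.116). TGFB2, a cytokine of the TGF-beta family, was 9.33 times higher, or 5.77 times with 50 units added before the log and 2.08 times at its second probe, and the stress-induced gene GADD45B was 1.88 times higher, whereas LATS2, a kinase that inhibits YAP, was 1.90 times lower.

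Of 16 genes of cholesterol synthesis, 13 were lower, 0 were higher and 3 did not pass, with the same numbers when adjusted over the list alone, and the median member was 1.56 times lower. INSIG1, a regulator of sterol sensing, was 3.30 times lower, and the enzyme genes HMGCS1 and MSMO1 were 2.00 times lower each. The list passed (camera adjusted p = 1.86e-05), though not with an estimated correlation (adjusted p = 0.413 with an estimated correlation). Without normalization 9 members were lower and 2 higher, and the median log2 change of -0.64 became -0.33. Of 27 hypoxia and glycolysis genes, 14 were lower, 1 was higher and 12 did not pass, against 16 and 1 when adjusted over the list alone. NDRG1, a stress-induced gene, was 5.83 times lower, MXI1, a MAX-binding repressor, 2.56 times lower and ALDOC, a glycolytic enzyme, 1.98 times lower. This list passed too (camera adjusted p = 0.000329), but not with an estimated correlation (adjusted p = 0.413 with an estimated correlation). Its median of -0.29 became -0.02 without normalization, in a setting where the median probe was 0.339 higher. Among 20 genes of mitochondrial respiration, 1 was higher, 1 was lower and 18 did not pass, with the same numbers when adjusted over the list alone (camera adjusted p = 0.839), and the median (-0.02) and mean (0.03) differed in sign. Without normalization 7 were higher and 0 lower, and with median centring 1 was higher and 6 lower. Cytochrome c, CYCS, was 1.51 times higher, and UQCRC1, a complex III subunit, was 1.16 times lower, a direction that turned without normalization (0.04, adjusted p = 0.498).

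Of 20 p53 targets measured, 14 were higher, 2 were lower and 4 did not pass, against 15 and 2 when adjusted over the list alone, and the median log2 change was 0.58. TP53INP1, which promotes cell death, was 2.51 times higher, the cell cycle inhibitor CDKN1A 1.81 times higher and the ribonucleotide reductase subunit RRM2B 1.79 times higher, while the kinase PLK3 was 1.47 times lower. The list passed (camera adjusted p = 5.9e-05), but not with an estimated correlation (adjusted p = 0.413 with an estimated correlation). Of 35 cell cycle genes, 7 were higher, 2 were lower and 26 did not pass, with the same numbers when adjusted over the list alone (camera adjusted p = 0.21). Without normalization 21 were higher and 0 lower, and with median centring 5 were higher and 7 lower, with a median of -0.04 against 0.07. The cyclins CCNE2 and CCNE1 were 1.56 and 1.41 times higher. Of 13 CDK inhibitors and D cyclins with their partners, 2 were higher, 4 were lower and 7 did not pass, against 3 and 5 when adjusted over the list alone (camera adjusted p = 0.523). The CDK inhibitor CDKN1C was 16.4 times, cyclin D1 (CCND1) 2.86 times and CDKN2D 2.42 times lower. In the BCL2 family, which controls apoptosis, 6 of 16 were higher, 6 were lower and 4 did not pass, against 8 and 7 when adjusted over the list alone (camera adjusted p = 0.618). The pro-apoptotic genes BMF and BCL2L11 were 3.16 and 1.78 times higher, although 3 of the other BCL2L11 probes did not pass.

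The unfolded protein and amino acid response and the NRF2 targets were mixed, while most of the called heat shock and RNA quality genes were lower. Of 24 genes of the unfolded protein and amino acid response, 7 were higher, 8 were lower and 9 did not pass, against 10 and 9 when adjusted over the list alone (camera adjusted p = 0.973), and the median (0.03) and mean (-0.06) differed in sign. DDIT4, an inhibitor of mTOR, fell by 1.59 on the log2 scale and the chaperone HSPA5 was 1.69 times lower, while ATF3 was 1.92 times and SESN2 1.53 times higher. Of 19 NRF2 targets, 5 were higher, 6 were lower and 8 did not pass, with the same numbers when adjusted over the list alone (camera adjusted p = 0.976). The aldo-keto reductases AKR1C1 and AKR1C3 were 7.79 and 3.32 times lower, and heme oxygenase, HMOX1, was 2.96 times higher. Second probes of both reductases were dim and did not pass. Of 12 heat shock and RNA quality genes, 8 were lower, 1 was higher and 3 did not pass, with the same numbers when adjusted over the list alone. FOS and FOSB, early response transcription factors rather than chaperones, were 3.24 and 1.47 times lower, FOS from 105 to 32.6 units (1.88 times with 50 units added). Without normalization 2 members of the list were higher and 2 lower, although the list passed there as lower, relative to other genes (camera adjusted p = 0.00546). It also passed with median centring (camera adjusted p = 0.00984). The chaperone HSPA1A was 1.51 times lower, a call lost without normalization (adjusted p = 0.0519). This list passed narrowly (camera adjusted p = 0.0338), but not with an estimated correlation (adjusted p = 0.645 with an estimated correlation), the mean of all probes of a gene (adjusted p = 0.091), the dimmest 50% left out (adjusted p = 0.114), or without parental replicate 1, parental replicate 2 or resistant replicate 1 (adjusted p = 0.0869, 0.0511 and 0.0508).

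Of 19 antigen presentation genes, 9 were higher, 5 were lower and 5 did not pass, with the same numbers when adjusted over the list alone (camera adjusted p = 0.618), and the median (0.18) and mean (-0.25) differed in sign. HLA-F, a class I gene, rose from 2099 ± 17.2 to 8519 ± 247 units (SD, n = 2), or 4.06 times, and its other probes were 4.05 and 2.39 times higher. The class II genes CD74 and HLA-DPA1 were 4.79 and 2.23 times lower, as were their second probes, 5.10 and 2.29 times. Of 30 interferon response genes, 11 were higher, 6 were lower and 13 did not pass, against 14 and 6 when adjusted over the list alone (camera adjusted p = 0.0811). Without normalization 21 were higher and 4 lower. GBP1, dim in parental cells at 37.8 units, was 4.93 times higher (2.69 times with 50 units added) and IFI6 2.20 times higher. OASL was 2.34 times and IFI44L 2.24 times lower, and the second probes of GBP1 and IFI44L did not pass. Of 25 NF-kB targets and inflammatory cytokines, 6 were higher, 11 were lower and 8 did not pass, against 7 and 12 when adjusted over the list alone. The cytokines IL24 and IL1B were 37.8 and 9.31 times lower (IL24 19.5 times with 50 units added), the prostaglandin synthase PTGS2 11.4 times and the chemokine CXCL3 3.96 times lower. This list did not pass (camera adjusted p = 0.116). It passed as lower, relative to other genes, without normalization (camera adjusted p = 0.000606) and with the dimmest 50% of probes left out (camera adjusted p = 0.0437). In the former setting its median turned from -0.15 to 0.12, but the median probe was 0.339 higher.

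**Figure D3:**
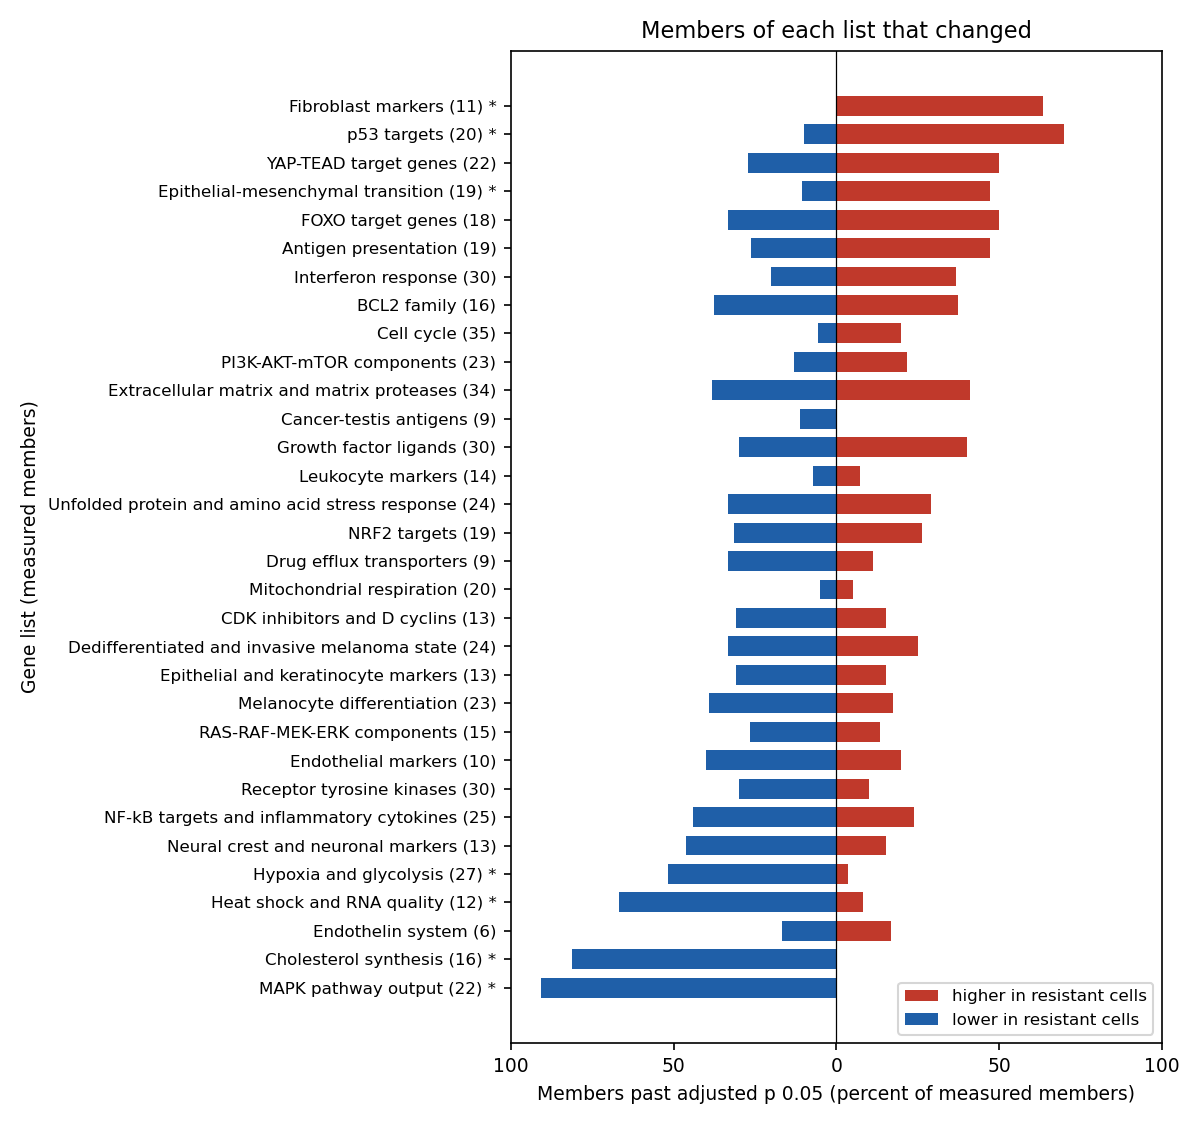
Share of the measured members of each of the 32 lists (number measured in brackets) that were higher (red, to the right) or lower (blue, to the left) in resistant cells at an adjusted p of 0.05, in percent, with lists ordered by their median change and an asterisk at the 7 lists past a camera adjusted p of 0.05. At the bottom 20 of 22 MAPK output genes and 13 of 16 cholesterol genes are lower, and at the top 7 of 11 fibroblast markers and 14 of 20 p53 targets are higher.

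The drug efflux, cancer-testis, leukocyte, epithelial and endothelial lists did not pass with camera, whereas the fibroblast markers above passed at the preset correlation. Of 9 drug efflux transporters, 1 was higher, 3 were lower and 5 did not pass, against 2 and 3 when adjusted over the list alone (camera adjusted p = 0.618). ABCC2 was 2.67 times lower and ABCA3 1.66 times higher. Of 9 cancer-testis antigens, 1 was lower, 0 were higher and 8 did not pass, against 0 when adjusted over the list alone (camera adjusted p = 0.618). That gene, PRAME, was 1.15 times lower while its other probes did not pass, a direction that turned without normalization (0.05, adjusted p = 0.609). Of 14 leukocyte markers, 1 was higher, 1 was lower and 12 did not pass, with the same numbers when adjusted over the list alone (camera adjusted p = 0.653), the higher one being LCP1. Of 13 epithelial and keratinocyte markers, 2 were higher, 4 were lower and 7 did not pass, against 3 and 4 when adjusted over the list alone (camera adjusted p = 0.618). The tight junction gene CLDN4 was 2.23 times and KRT7 1.74 times lower, and the mucin MUC1 was 1.68 times higher. Of 10 endothelial markers, 2 were higher, 4 were lower and 4 did not pass, with the same numbers when adjusted over the list alone (camera adjusted p = 0.618). The angiopoietin receptor TEK was 2.17 times higher and ROBO4 2.76 times lower. None of the 7 lists past the threshold had a median of the other sign under another scaling, whereas 12 other lists did without normalization and 4 did with median centring. Counts of members moved with the scaling too. Without normalization 10 lists with more lower than higher members had more higher ones, among them the receptor tyrosine kinases (8 higher, 6 lower) and the RAS-RAF-MEK-ERK components (5 higher, 1 lower). In the same setting 9 members of the BCL2 family were higher and 1 lower, 16 growth factor ligands were higher and 5 lower, and 5 leukocyte markers were higher and 1 lower. With median centring the balance turned in the cell cycle and extracellular matrix lists.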

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

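The crossed pairing and the fit without probes at the ceiling or at 0 were chosen after the data were seen. In the 14 alternative settings the EDN1 change lay between 4.03 and 4.74, and it passed the threshold except with an array left out, when the log2 change was 4.39 to 4.52 and the adjusted p 0.061 to 0.0683. Without normalization between arrays, 12274 probes were higher and 1870 lower, and 1631 and 589 were so by at least 2-fold. That setting also turned the sign of UQCRC1 (0.04281), ABCC4 (0.01541) and PRAME (0.05484), none of which then passed, and of 5 named genes that passed in neither, AKT2 (0.24), ECE1 (0.13), COX5A (0.15), ATP5F1A (0.0073) and CD3D (0.02), in a setting where the median probe was 0.339 higher. With the dimmest 50% of probes left out, 380 probes were at least 2-fold higher and 524 lower, fewer because fewer were tested. An offset of 50 units, which shrinks folds of dim probes by construction, left 472 and 568. A test against a 1.5-fold change left 652 higher and 848 lower. With any 1 array left out the limma calls were lost. The fit then has 1 residual degree of freedom, and the lone array is assumed to vary like the other group. The block fits below also have 1 residual degree of freedom and kept calls. That alone is therefore not why the calls were lost, and the cause of the loss was not tested. The directions of all 145 named genes held with each array left out. This was nearly fixed in advance, because their groups did not overlap. The replicate number did not pair the arrays, since deviations of same-numbered arrays correlated at -0.129. As a replicate block it left 1235 probes higher and 1405 lower, and 23 named genes that passed without it, among them MITF, ECE2, PIK3R1 and CYCS, did not pass there (adjusted p = 0.107, 0.0641, 0.0604 and 0.0558). The cause was not tested. The crossed pairs as a block gave 3436 and 3511. Of the gene lists, 7 passed with camera, 0 with an estimated correlation and 30 with fry. The direction of fry was opposite to that of camera for the endothelin system (median -0.3385), antigen presentation (median 0.1826), the unfolded protein and amino acid response (median 0.03328), and, with neither test passed, for mitochondrial respiration (fry adjusted p = 0.582), all lists whose median and mean differ in sign. MAPK output, cholesterol synthesis, hypoxia and glycolysis, and p53 targets passed with camera under all 14 settings of the fit, the highest adjusted p being 6.96e-10, 0.000234, 0.00541 and 0.00546. Over the same settings the adjusted p lay between 0.00453 and 0.207 for the epithelial-mesenchymal transition, between 0.00546 and 0.114 for heat shock and RNA quality, and between 0.000189 and 0.0627 for fibroblast markers. Signal over background limits the dimmest probes most: 443 lay at or below 0 on at least 1 array.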

Other observations

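The gene families, chromosome and probe classes described here were chosen after their values were seen, and so were all tests but that of failed spots on single arrays. The camera adjusted p-values of the families make no allowance for that choice. Of 15 contractile genes of smooth muscle, 10 were higher in the resistant line, 2 were lower and 3 did not pass (camera adjusted p = 0.000334 over 5 such families, 0.122 with an estimated correlation). Of the 15, 5 also belong to the lists above. Among them are TAGLN, MYL9, CNN1 and ACTA2 of the epithelial-mesenchymal transition list, so the results for that list and this family overlap. KCNMB1, a potassium channel subunit of smooth muscle, rose from 54.7 to 1121 units, ACTA2 from 1209 to 12570 units and ACTG2 from 32.4 to 408 units. The fibroblast markers were higher in the same arrays, 7 of 11 with 0 lower, as they were beside the complement family below. DES and MYH11, 2 further markers of smooth muscle, were dim and did not pass (adjusted p = 0.206 and 0.141). Of 22 complement genes, 9 were higher, 1 was lower and 12 did not pass (camera adjusted p = 0.00813, 0.122 with an estimated correlation). The proteases C1S, C1R and CFI were 5.59, 4.62 and 4.69 times higher, and CFB and CLU were 3.63 and 3.61 times higher. The complement family did not pass without normalization (adjusted p = 0.101).

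Of 18 genes of the interleukin-1 family and its receptors, 9 were lower, 0 were higher and 9 did not pass (camera adjusted p = 7.99e-05, 0.122 with an estimated correlation), and the family's median of -0.39 had the other sign, at 0.01, without normalization, where the median probe was 0.339 higher. IL1RL1, the receptor of interleukin-33, fell from 12700 to 362 units, and IL1A and IL1R1 were 3.55 and 2.61 times lower. Of 19 S100 calcium-binding genes, 9 were lower, 0 were higher and 10 did not pass (camera adjusted p = 0.000334, 0.122 with an estimated correlation), with S100P falling from 684 to 29.4 units. S100A6 read at the scanner ceiling on all 4 arrays and S100A4 on both parental arrays, so no change could be seen in the first and a fall of the second would be understated. Of 11 genes of adhesion to laminin, 8 were lower, 2 were higher and 1 did not pass (camera adjusted p = 0.00813, 0.122 with an estimated correlation). The family holds the laminin chains LAMA3 and LAMB3 and the cytoskeletal linkers PLEC and DST as well as receptors. ITGB4 and ITGA6, whose products pair as a laminin receptor, were 3.71 and 3.50 times lower.

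Genes on chromosome 13 were lower together. Its 182 genes in the brighter part of the array had a median change of -0.27, with 93 lower and 18 higher. The medians of the 22 other chromosomes lay between -0.055 and 0.103. None of 10000 random gene sets of like brightness had a median as low (permutation p = 1e-04, the smallest they can give). That p-value treats genes as independent and makes no allowance for choosing the chromosome by its low median. It measures the spread between genes, not between cultures. Quantile normalization was not the source, since without it the chromosome lay at -0.31 relative to all bright genes, nor were a few neighbours, since the 6 successive runs of 30 genes had medians from -0.40 to -0.21. In all, 78.6% of its genes lay below 0, which is consistent with fewer copies of the chromosome in the resistant line, a hypothesis found on these data. No DNA was analysed here, so a chromosome lost during selection, or a subclone of the parental cells that already lacked it, stays open.

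The fall of the MAPK output genes does not rest on the scaling of the arrays or on dim probes. Relative to all bright genes the list's median was -1.72 without normalization, and with 50 units added before the log it was -1.54. Of 12 heat shock and RNA quality genes, 8 were lower in the same arrays, among them FOS and FOSB. Without normalization 2 of that list were higher and 2 lower, although the list passed there as lower, relative to other genes (camera adjusted p = 0.00546). The 20 MAPK output genes that fell may reflect inhibitor present in the medium at harvest, or a change of the line that lasts without it. These cannot be told apart, because the medium at harvest is not given in the sources used here. No array is known to be of resistant cells without drug, or of parental cells with it.

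Some probes were near 0 in one line and clear in the other: 17 were below 10 normalized units on both parental arrays and above 100 on both resistant arrays, and 15 the reverse. Spots that failed on single arrays would put the low arrays in different lines in 66.7% of cases if all arrays failed alike, or in 55.3% at the unequal rates of the spots low on 1 array, but 3 of 35 probes low on 2 arrays had them there (8.57%, exact binomial p = 1.1e-12 and 8.6e-09). Of 13 such genes with another probe above 50 units, that probe changed at least 2-fold the same way in 6 (46.2%; JPH2, GFRA1, DMRT2, ST8SIA1, ADGRF1 and SLITRK6), against at most 4.05% in either direction for the brightest probe of 4796 other genes with several probes (one-sided exact binomial p = 5.88e-06), so an effect on the single probe is not the cause in all 13. Among genes with other changes of at least 8-fold, more had a second probe that followed, 17 of 19 (two-sided Fisher's exact test p = 0.015). For the other 7 (ZNF548, SH3BP4, PLXNA1, ANKRD26, KIF13A, SEMA4G and NFATC1, of which SH3BP4 and NFATC1 lay just under the 2-fold limit), an effect on the probe cannot be told apart from a change in 1 transcript of the gene, since probe sequences were not used here.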
